A study of Mus musculus with 5 samples.

How the data were processed

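The study profiled RNA of CD11b+Gr1+ myeloid cells sorted from mouse lungs. CD11b (the integrin chain encoded by Itgam) and Gr1 (an epitope of the Ly6 proteins of neutrophils and inflammatory monocytes) together mark granulocytic and monocytic cells, so a library holds a mixture of both. Per the labels' protocols, wild-type mice received 5000000 LLC-RFP cells under the skin (LLC is the Lewis lung carcinoma line of the mouse, RFP a red fluorescent protein) and were compared 9 days later with unchallenged wild-type mice, and about 100000 cells were sorted for each RNA sample. Per the labels' protocols, total RNA was amplified by a whole-transcript method for picogram inputs, converted to sense-strand cDNA with an exon-array module, fragmented and labelled with biotin. The design text describes 3 control and 2 tumour-challenged samples, and 1 array was given for each.

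The deposited values are log2 expression values, 1 per array for each of 16661 probe sets, made with RMA per the submitters' processing notes. RMA subtracts background from each array, quantile-normalizes the probe signals and summarises them by median polish. Its version, the choice of probe sets and any filter are not given in the sources used here. The submitters' processing notes also name the mouse genome build mm8 without saying what it was used for, so no coordinates are printed. All arrays share the same lowest value of 4.09, and 48 probe sets lie at that value on at least 1 array. Of the probe sets above it, 3259 (19.6% of all) have exactly equal values on 2 or more arrays. This makes some within-group spreads very small or 0. After the deposited normalization the arrays still differed in their upper quartile, which ran from 7.90 in control replicate 3 to 8.23 in tumour-challenged replicate 1.

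Probe sets were named from the platform's annotation: 14939 carry 1 gene symbol, 989 carry several and were not assigned to a gene, and 733 are unnamed here. Symbols were brought up to date through the gene number, which matched for 14884 of the 14939. Where a gene had several probe sets, the one with the highest mean over the 5 arrays stood for it in gene lists, which left 14807 genes.

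The main test was a linear model with moderated variances (limma 3.58.1, R 4.3.3) on the deposited log2 values, tumour-challenged minus control, 2 against 3 arrays, two-sided, with Benjamini-Hochberg adjustment over all 16661 probe sets and a threshold of 0.05. The fit has 3 residual degrees of freedom and estimated 1.36 prior degrees of freedom. The design text states that group means were compared and that genes more than 2-fold up were taken. This 2-fold rule was applied as a description without a test, and was extended here to lower genes. Both directions were counted. It was noted whether all tumour-challenged arrays lay beyond all control arrays, which chance gives for 10% of probe sets in each direction. Gene lists fixed in advance (25 lists, 421 of 546 listed genes measured) were tested with camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists. Alternatives with a correlation estimated from the data, and with fry, were also run. The lists are primary granule, secondary and tertiary granule, mature neutrophil, monocyte, cell cycle, interferon-stimulated, MHC class II, suppressive myeloid, matrix and angiogenesis, inflammatory cytokine and NF-kB, alternative activation, hypoxia and glycolysis, immediate-early stress, ribosomal protein and oxidative phosphorylation genes. The other 10 hold markers of other cells that the gate could hold: erythroid, B, T and NK, lung epithelial, endothelial, fibroblast, alveolar macrophage, dendritic, eosinophil with basophil and mast, and platelet. Of the 421 measured genes 28 stand in more than 1 list, among them 4 of 16 secondary and tertiary granule genes, 1 of 22 interferon-stimulated genes, 5 of 16 alveolar macrophage genes and 8 of 27 matrix genes. Cross-hybridisation between close paralogs, such as those of Ifi205, Fpr-rs7 and Defb37, was not tested.

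Named genes followed a rule fixed at the same time. The 10 largest changes per direction among genes past the threshold with separate arrays were to be named. Where fewer passed, the places were filled from genes past 2-fold whose arrays did not overlap, which is what happened here for every place. Up to 4 members of each list with the largest change, and 15 genes tied to the study's topic, were added. Of those 15, Ly6g had no probe set with a single symbol and is not analysed here.

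On simulated data with the real probe set means and with variances drawn from the fitted prior (20 simulations of 16661 probe sets, 200 changed), the test recovered 58.7% of changes of 1 log2 unit, 85.4% of changes of 2 and 90.9% of changes of 3, with a mean of 9.05 false calls. A first version of this simulation drew its spreads from the moderated variances. It recovered more, and was replaced as too optimistic. The recovered shares hold for 200 changed probe sets of 1, 2 and 3 log2 units. With fewer or smaller changes the adjustment is stricter, and the real data had only 46 probe sets past 2-fold. The shares therefore do not give the power of the test on the real data. The list test recovered a simulated shift of -0.5 log2 in the interferon list in 100% of the simulations and called 0.42% of unchanged lists, with genes simulated as independent.

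The number of arrays limits the precision: the median standard error of a log2 difference was 0.122. Arrays have no read depth. A background level of 6.87 was set, after the data had been seen, at the 95th percentile of the mean values of 970 probe sets for olfactory, vomeronasal and taste receptors, and 49.2% of all probe sets lay above it. Pearson correlations between arrays ran from 0.973 to 0.991, and control replicate 3 had the lowest median correlation with the others (0.979). No pair of arrays was identical. The labels do not say whether samples came from separate mice or pools, so the limma p-values measure only the spread between these samples, which may be technical. The camera p-values with the preset correlation compare the genes of a list with the other genes. They do not measure how a list varies between samples. The labels number replicates in both groups without saying that a number marks a shared day or litter, so the main fit has no block. Scan dates and slides are not given in the sources used here.

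Alternatives tried were centring each array on its median, quantile normalization of the deposited values, leaving out the dimmest 25% of probe sets, leaving out each array in turn, a block for the replicate number, array weights, an intensity trend with robust variances, 1 probe set per gene, means of linear values for the 2-fold rule, and averaging the probe sets of a gene for the lists. These were set before the data were examined. An offset of 16 before the logarithm, set at the same time, was not run, because the values are already log2. The background level and 3 further gene lists (sterol synthesis, MHC class I processing and granule-stage genes) were added after the data had been seen.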

Results

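Gene expression was measured in CD11b+Gr1+ cells sorted from the lungs of mice that carried a subcutaneous LLC-RFP tumour for 9 days (2 arrays) and of unchallenged control mice (3 arrays). The comparison asks how a tumour growing at a distant site alters the transcripts of myeloid cells in the lung. Values are log2 RMA expression values for 16661 probe sets. Array medians lay between 6.77 and 6.88, and the median difference over all probe sets was 0.024 log2. Genes that mark the sorted population were bright in both groups. Itgam, which encodes CD11b, had a mean of 10.77 ± 0.16 (SD, n = 3) in controls and 10.96 ± 0.21 (SD, n = 2) after tumour challenge. The calcium-binding proteins S100a8 and S100a9 had control means of 12.19 ± 0.10 and 12.75 ± 0.11 (SD, n = 3). Bright values were not limited to such genes. Sftpc, a lung epithelial gene, was at 11.74 ± 0.64 (SD, n = 3) in controls and 12.24 ± 0.06 (SD, n = 2) after tumour challenge.

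The largest differences toward the tumour-challenged samples were in versican, in genes of neutrophil granules and in the acute-phase gene Saa3. Vcan, the gene of the matrix proteoglycan versican (probe set 6814956), was 4.69-fold higher, at 10.68 ± 0.59 (SD, n = 2) against 8.45 ± 0.21 (SD, n = 3), a log2 difference of 2.23 ± 0.29 (SE). Ngp, neutrophilic granule protein (probe set 6992436), was 4.34-fold higher with a log2 difference of 2.12 ± 0.18 (SE). Ltf, the iron-binding lactoferrin (probe set 6992482), differed by 1.83 ± 0.10 (SE) from a control mean of 6.81, which is not above the background level of 6.87 (set from probe sets of chemosensory receptors), and Lcn2, the siderophore-binding lipocalin 2 (probe set 6885873), was 3.19-fold higher with a difference of 1.67 ± 0.17 (SE). None of these passed the test over all probe sets (limma with Benjamini-Hochberg adjustment: adjusted p of 0.537, 0.517, 0.495 and 0.517).

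Over all probe sets, limma called 0 higher and 0 lower at an adjusted p under 0.05, and the smallest adjusted p was 0.495. At an unadjusted p under 0.05 there were 597 higher and 493 lower, 1090 in all, where chance alone gives about 833. That excess is not specific to the groups, since 3 of the other ways to split the 5 arrays into 2 and 3 gave more (1752, 1406 and 1229). Without tumour-challenged replicate 2 there were 1256 higher, and without tumour-challenged replicate 1 there were 1008 lower. With an intensity trend and robust variances 0 passed. With each array centred on its median, 1 probe set passed, that of Ltf (adjusted p = 0.0254 by limma).

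By the submitters' rule of group means more than 2-fold up, 24 probe sets were higher. With the same rule extended to the other direction, 22 were lower. The arrays of the groups did not overlap for 22 of the 24 and 18 of the 22. Picking probe sets by a large difference of means favours separate arrays. With tumour-challenged replicate 1 and control replicate 3 set against the rest, 15 of 19 probe sets past 2-fold did not overlap either. Over all probe sets the arrays did not overlap for 11.2% higher and 7.8% lower, near the 10% that chance gives in each direction. After quantile normalization 17 probe sets were higher and 28 lower by the 2-fold rule. These counts depended on single arrays: 57 were higher without tumour-challenged replicate 2, 75 were lower without tumour-challenged replicate 1, and 45 were lower without control replicate 2.

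The 10 genes with the largest positive differences included 3 whose tumour-challenged arrays stood far apart. Saa3, an acute-phase serum amyloid that ranks between Ltf and Lcn2, differed by 1.73 ± 0.51 (SE) on the log2 scale, Camp, the antimicrobial peptide cathelicidin, by 1.56 ± 0.44, and Flt3, a receptor tyrosine kinase of progenitors and dendritic cells, by 1.27 ± 0.49. The 2 tumour-challenged values were 9.01 and 7.40 for Saa3, 7.58 and 8.93 for Camp, and 9.51 and 7.99 for Flt3. The control means of Saa3 (6.48) and Camp (6.69) lay below the background level. Without tumour-challenged replicate 1 the differences of Saa3 and Flt3 were 0.92 and 0.52, and without tumour-challenged replicate 2 that of Camp was 0.89. Emp1, a membrane protein gene, differed by 1.16 ± 0.21 (SE). Pcgf1, a Polycomb group gene, differed by 1.12 ± 0.54 (SE), and by 0.62 without control replicate 3. Fpr-rs7, of the formyl peptide receptor family, differed by 1.12 ± 0.32 (SE) but lay below the background level in both groups.

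The 10 genes with the largest negative differences included Ifi205 and Ifit2, which interferons induce. Unc93a was lower, at 5.96 ± 0.19 (SD, n = 2) against 7.85 ± 0.31 (SD, n = 3), a log2 difference of -1.89 ± 0.21 (SE). Ccr3, the eotaxin receptor, differed by -1.48 ± 0.31 (SE), Ifi205, an interferon-activated gene of a family of close paralogs, by -1.36 ± 0.31, and Ifit2, an interferon-induced antiviral gene, by -1.28 ± 0.15. Clec9a, a C-type lectin of cross-presenting dendritic cells, differed by -1.17 ± 0.26 (SE). Slbp, which binds the stem-loop of histone mRNA, differed by -1.36 ± 0.48 and by -0.91 without tumour-challenged replicate 2. Fabp1 differed by -1.15 ± 0.15 and Serpinb2 by -1.11 ± 0.14 (SE). Polr2h (-1.27 ± 0.41, with 1 tumour-challenged array at the lowest value) and Defb37 (-1.12 ± 0.11) lay below the background level in both groups. The limma adjusted p of these 20 genes ran from 0.495 for Ltf to 0.810 for Pcgf1. The tumour-challenged means of Unc93a, Ccr3, Slbp, Fabp1 and Serpinb2 lay below the background level, so their differences are measured against a group at background. A probe set shared by Ifit3 and Ifit3b, outside the naming rule and picked after its values were seen, differed by -2.17 ± 0.49 (SE), and its tumour-challenged values (6.46 and 5.03) lay below the background level.

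**Figure D1:**
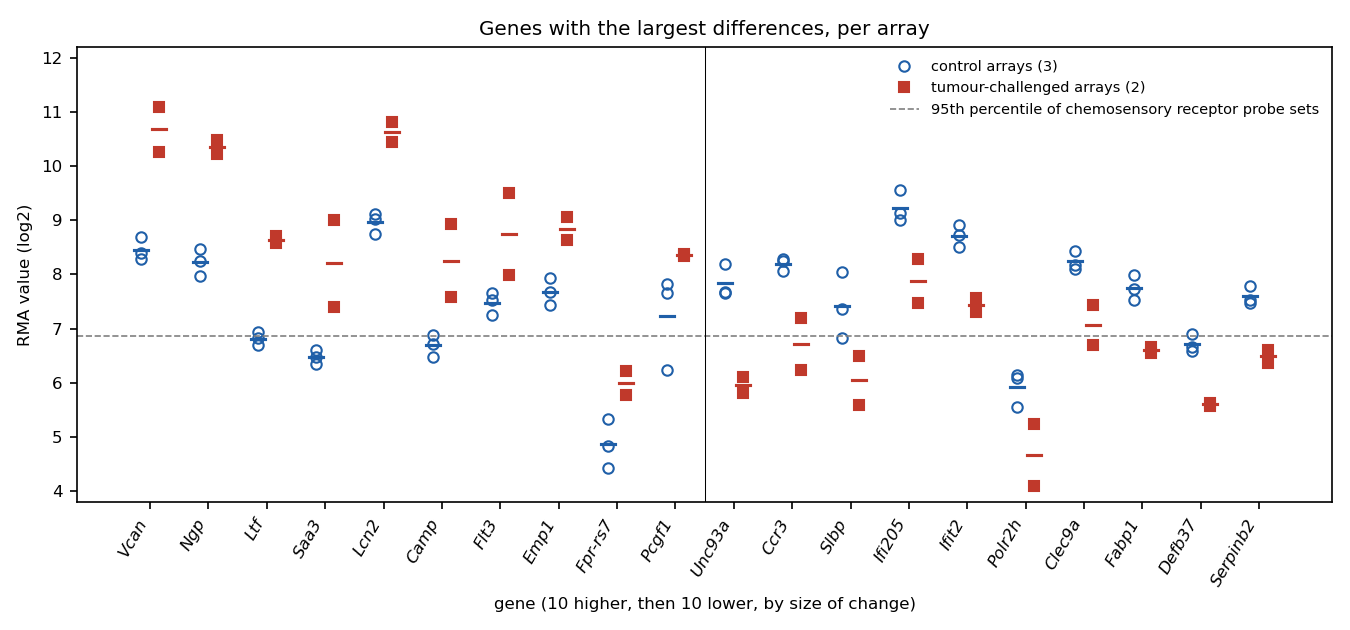
RMA values (log2, vertical axis) of the 10 genes with the largest positive and the 10 with the largest negative difference whose arrays did not overlap (horizontal axis); circles are the 3 control arrays, squares the 2 tumour-challenged arrays, short bars group means, and the dashed line the background level of 6.87. The tumour-challenged values of Ltf (8.71 and 8.58) lie close together, while those of Saa3, Camp and Flt3 lie far apart.

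Genes of the secondary and tertiary granules were higher as a group after tumour challenge. Of the 16 measured members 15 had a positive difference, for 12 of them the arrays did not overlap, and the median difference was 0.59 log2 (camera, adjusted p = 3.56e-08 with the preset correlation and adjusted p = 0.357 with an estimated correlation). No member passed the test over all probe sets, and 3 (Ngp, Ltf and Lcn2) passed when adjusted over the list alone. That adjustment does not allow for the number of lists, and 12 of the 25 lists had such a member. Mmp8, neutrophil collagenase, differed by 1.03 ± 0.27 (SE) and the gelatinase Mmp9 by 0.29 ± 0.18. Without control replicate 3 the list's median difference was 0.35. Oxidative phosphorylation genes, listed as a sign of RNA quality, had a median difference of 0.30 (camera adjusted p = 2.62e-04, adjusted p = 0.713 with an estimated correlation, and a median of 0.10 with adjusted p = 0.300 without tumour-challenged replicate 1). The array medians of both lists were highest in tumour-challenged replicate 1 (0.725 for granule and 0.471 for oxidative phosphorylation genes, against the control mean) and lowest in control replicate 3 (-0.212 and -0.237). In tumour-challenged replicate 2 and control replicate 1 they differed in order, with 0.460 and 0.113 for granule genes and 0.102 and 0.239 for oxidative phosphorylation genes. Of the primary granule genes, formed earlier in neutrophil development, 5 of 9 had a positive difference and the list did not pass (median 0.09, camera adjusted p = 0.602). Prtn3 (0.69 ± 0.10, SE) and Ctsg (0.33 ± 0.08, SE), which encode the granule proteases proteinase 3 and cathepsin G, passed when adjusted over the list alone, with Ctsg below the background level in both groups. Mpo, myeloperoxidase, differed by -0.75 ± 0.28 (SE), and by -0.36 without tumour-challenged replicate 2.

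Markers of mature neutrophils did not move in 1 direction as a group. The arrays did not overlap for 4 of them that were higher and 3 that were lower. The median difference over 17 members was 0.01 log2 and the mean 0.07, while the test pointed down (camera adjusted p = 0.922), and its direction changed with centring or quantile normalization (both -0.02). The chemokine receptor Cxcr2 differed by -0.12 ± 0.11 (SE), the G-CSF receptor Csf3r by -0.22 ± 0.14 and Il1b by -0.28 ± 0.15. S100a8 and S100a9 differed by -0.08 ± 0.13 and -0.08 ± 0.11 (SE). Wfdc21 differed by 1.03 ± 0.14 (SE) and was the 1 member to pass when adjusted over the list alone. G0s2 differed by 0.49 ± 0.15 and Csf2rb by 0.46 ± 0.20 (SE), the latter by 0.24 without tumour-challenged replicate 1. Clec4d differed by -0.39 ± 0.17 (SE), and by -0.21 without tumour-challenged replicate 2. Monocyte genes did not pass as a list either (15 measured, median 0.07, camera adjusted p = 0.251). Vcan passed when adjusted over that list alone. F13a1, a coagulation factor chain, and Fn1, fibronectin, differed by 0.79 ± 0.34 and 0.65 ± 0.24 (SE), or 0.44 and 0.36 without tumour-challenged replicate 1, and the monocyte chemokine receptor Ccr2 by 0.04 ± 0.19.

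Interferon-stimulated genes were lower after tumour challenge. All 22 measured members had a negative difference, the arrays did not overlap for 17, and the median was -0.48 log2 (camera, adjusted p = 2.33e-15 with the preset correlation and adjusted p = 0.357 with an estimated correlation of 0.595). Ifit2 and Rsad2, the antiviral enzyme viperin (-0.91 ± 0.14, SE), passed when adjusted over the list alone, and none did over all probe sets. Mx2, a dynamin-like antiviral GTPase, differed by -0.81 ± 0.23 and the chemokine Cxcl9 by -0.66 ± 0.15 (SE). B-cell, dendritic cell and alveolar macrophage markers, given below, were lower in the same samples (medians -0.43, -0.19 and -0.12, each with camera adjusted p = 0.357 with an estimated correlation). Those cells express interferon-stimulated genes too.

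MHC class II genes, which present antigen to helper T cells, were also lower (7 measured, 6 negative, median -0.29, camera adjusted p = 2.62e-04, and adjusted p = 0.357 with an estimated correlation). Cd74, the invariant chain, differed by -0.79 ± 0.13 (SE), H2-Ab1 by -0.70 ± 0.16 and H2-Aa by -0.70 ± 0.14, and these 3 passed when adjusted over the list alone. The main median is the value of H2-Ea, which lay below the background level in both groups, and H2-Oa had a tumour-challenged mean below it. The median was -0.45 when the dimmest 25% of probe sets were left out. B cells and dendritic cells express these genes too, and markers of both were lower in the same samples, as were those of alveolar macrophages.

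Of the B-cell markers 13 of 14 had a negative difference (median -0.43, camera adjusted p = 9.77e-11, and adjusted p = 0.357 with an estimated correlation). The CD20 gene Ms4a1 differed by -0.81 ± 0.19 (SE), Fcer2a by -0.81 ± 0.16 and the transcription factor gene Pax5 by -0.70 ± 0.18, and 8 members passed when adjusted over the list alone. Of these 8, Vpreb3 lay below the background level in both groups, and Cd22, Cr2 and Ms4a1 had tumour-challenged means below it. The brightest member, Cd79b, differed by -0.29 ± 0.22 (SE) with overlapping arrays. Dendritic cell markers were lower (16 measured, 12 negative, median -0.19, camera adjusted p = 2.62e-04, and adjusted p = 0.357 with an estimated correlation), while Flt3, Tcf4, Siglech and Ccl22 had positive differences (1.27, 0.23, 0.00 and 0.00). The dendritic median was -0.32 without tumour-challenged replicate 1 and -0.12 without tumour-challenged replicate 2. Alveolar macrophage markers were lower (16 measured, 11 negative, median -0.12, camera adjusted p = 5.5e-05, and adjusted p = 0.357 with an estimated correlation), and 5 passed when adjusted over the list alone, among them lipoprotein lipase, Lpl (-0.83 ± 0.18, SE), and the mannose receptor Mrc1 (-0.48 ± 0.09, SE). The macrophage median was -0.20 without either tumour-challenged replicate.

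Markers of other cells were higher in the tumour-challenged samples. Lung epithelial markers were higher in 16 of 18 members (median 0.29, camera adjusted p = 9.99e-04, and adjusted p = 0.357 with an estimated correlation), with the surfactant genes Sftpa1 and Sftpc at 0.89 ± 0.37 and 0.50 ± 0.40 (SE). Erythroid markers were higher in 6 of 8 members (median 0.13, camera adjusted p = 0.0263, and adjusted p = 0.357 with an estimated correlation). Carbonic anhydrase 2, Car2, differed by 1.09 ± 0.25 (SE) and the haem synthesis enzyme Alas2 by 0.84 ± 0.19, and both passed with Slc4a1 when adjusted over the list alone. The other 3 positive members, Epb42, Ermap and Klf1, lay below the background level in both groups. Both lists lost their call without control replicate 1 (adjusted p of 0.0713 for epithelium and 0.0845 for erythroid) and without tumour-challenged replicate 2 (0.0853 and 0.402).

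Oxidative phosphorylation genes, which encode the mitochondrial respiratory chain and were listed in advance as a sign of RNA quality, were higher in 18 of 18 measured members (median 0.30, camera adjusted p = 2.62e-04, and adjusted p = 0.713 with an estimated correlation of 0.787). Examples are Ndufv1 at 0.44 ± 0.31 and Sdhc at 0.42 ± 0.26 (SE), but Ndufv1 was at 0.09 without tumour-challenged replicate 1 and Sdhc at 0.19 without control replicate 3. The arrays did not overlap for 3 of the 18, and without tumour-challenged replicate 1 the median was 0.10 with a camera adjusted p of 0.300. Inflammatory cytokine and NF-kB genes were lower by the test (24 measured, 15 negative, median -0.06, camera adjusted p = 0.0311, and adjusted p = 0.726 with an estimated correlation). Il1a, interleukin 1 alpha, differed by -0.79 ± 0.15 (SE) and Ier3, an early response gene, by 0.63 ± 0.21. Without control replicate 2, control replicate 3 or tumour-challenged replicate 2 this list did not pass (adjusted p of 0.0814, 0.0809 and 0.854, with medians of 0, -0.12 and 0.02).

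Genes tied to suppressive myeloid cells did not pass as a list (22 measured, 11 positive and 11 negative, median -0.01, camera adjusted p = 0.170). Arg1, arginase 1, differed by -0.19 ± 0.09 (SE) and Nos2, inducible nitric oxide synthase, by 0.04 ± 0.07, with Nos2 below the background level in both groups. Tgfb1 differed by -0.15 ± 0.22. Il10 differed by -0.85 ± 0.26, or -0.50 without tumour-challenged replicate 2, the checkpoint ligand gene Cd274 by -0.70 ± 0.13 and the cystine transporter gene Slc7a11 by -0.66 ± 0.06 (SE). Ncf4 differed by 0.56 ± 0.25 (SE), or 0.25 without tumour-challenged replicate 1. In this list the arrays did not overlap for 2 members that were higher and 4 that were lower. Slc7a11 passed when adjusted over the list alone. Genes of matrix, angiogenesis and metastasis did not pass (27 measured, 12 positive and 15 negative, median -0.01 and mean 0.13, with the test pointing down, camera adjusted p = 0.613). Vcan passed when adjusted over this list alone. Tgfbi differed by 0.66 ± 0.30 (SE), the angiogenic factor gene Vegfa by -0.17 ± 0.08 and Prok2, prokineticin 2, by -0.09 ± 0.06.

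The other lists did not pass. Cell cycle genes had a median of -0.01 (31 measured, camera adjusted p = 0.113), with the proliferation markers Mki67 at -0.33 ± 0.16 and Top2a at -0.35 ± 0.15 (SE). Cenpa was at -0.39 ± 0.13 (SE), while Ube2c, below the background level in both groups, was at 0.48 ± 0.14. The arrays did not overlap for 5 cell cycle genes that were higher and 4 that were lower. Hypoxia and glycolysis genes had a median of 0.15 (adjusted p = 0.113) and alternative activation genes one of 0.00 with a mean of -0.09 (test pointing down, adjusted p = 0.122). Immediate-early stress genes, a sign of handling, had a median of -0.03 (adjusted p = 0.113) and ribosomal protein genes, a sign of RNA quality, one of 0.10 (11 measured, adjusted p = 0.406). Among cell markers, eosinophil, basophil and mast cell genes had a median of -0.06 (adjusted p = 0.0826), and 4 passed when adjusted over the list alone: Mcpt8 (0.98 ± 0.13, SE), a basophil protease, and Prg2 (0.83 ± 0.18, SE), eosinophil major basic protein, were higher, while Ccr3 was lower and Il5ra had a negative difference below the background level in both groups. T and NK cell genes (median -0.04, adjusted p = 0.122), endothelial genes (median -0.05, adjusted p = 0.162), fibroblast genes (median 0.01, mean -0.01, test pointing down, adjusted p = 0.922) and platelet genes (median 0.05, adjusted p = 0.616) did not pass. The platelet chemokine genes Pf4 and Ppbp differed by 1.10 ± 0.54 and 1.00 ± 0.39 (SE), and by 0.38 and 0.45 without tumour-challenged replicate 1.

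Other named values also moved by more than 1.5 times when 1 array was left out. Without tumour-challenged replicate 1, Mmp8 was at 0.64, Tgfbi at 0.40, Ier3 at 0.37, Itgam at 0.04 and Arg1 at -0.12. Without tumour-challenged replicate 2, Cxcl9 was at -0.43, Polr2h at -0.69, Mki67 at -0.17, Top2a at -0.22, Csf3r at -0.10, Il1b at -0.09 and Cxcr2 at 0.00. Without control replicate 3, Mmp9 was at 0.12 and Sftpc at 0.24. Car2, Alas2, Slc4a1, Prtn3, Mcpt8, Prg2 and Pf4 had control means below the background level, and Ms4a1, Cxcl9 and Arg1 had tumour-challenged means below it.

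**Figure D2:**
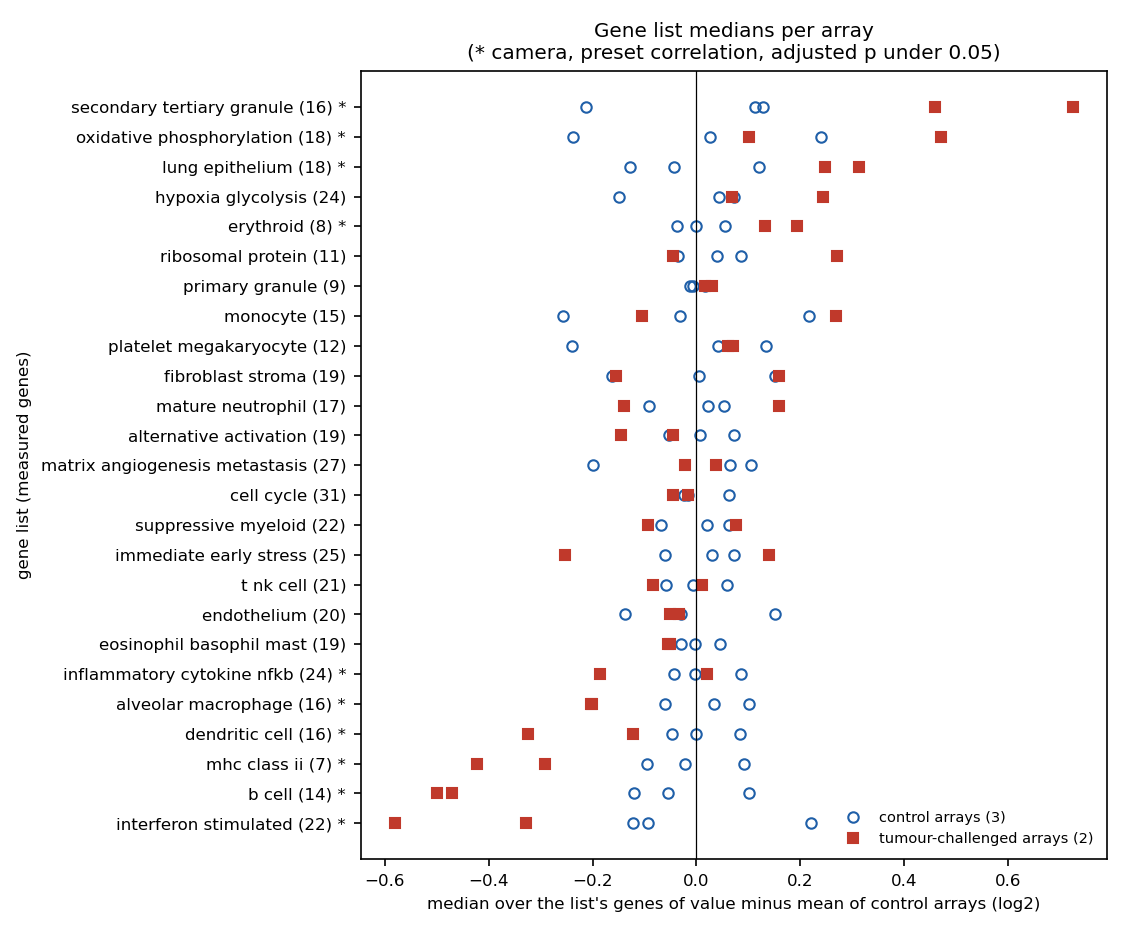
Median over each list's measured genes (count in brackets) of the array's value minus the control mean (log2, horizontal axis), 1 row per list; circles are the 3 control arrays and squares the 2 tumour-challenged arrays. For 8 of the 10 lists that passed camera with the preset correlation, marked with an asterisk, both tumour-challenged arrays lie beyond all control arrays; oxidative phosphorylation and inflammatory cytokine genes are the exceptions.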

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

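The alternatives named here were set in advance, and only the background level was added after the data were seen. Counts over all probe sets stayed at 0 higher and 0 lower in all settings, except 1 higher (Ltf) with each array centred on its median. Over the fits without 1 array they were 0 to 0, the 2-fold counts 17 to 57 higher and 23 to 75 lower, and the list calls 2 to 4 higher and 5 to 8 lower. With 1 tumour-challenged array left, that array is assumed to vary like the controls. With 1 probe set per gene, 14 were lower by the 2-fold rule, since probe sets with several or no symbols drop out. Of the 46 probe sets past 2-fold, 43 remained after centring and 39 after quantile normalization, but only 29 without tumour-challenged replicate 1, 31 without control replicate 3 and 32 without tumour-challenged replicate 2. The list calls (4 higher, 6 lower) fell to 0 and 0 with an estimated correlation and to 0 and 0 with fry, with the medians unchanged: 0.59 for secondary granule, -0.48 for interferon, -0.29 for MHC class II, -0.06 for inflammatory, 0.30 for oxidative phosphorylation, 0.13 for erythroid, -0.43 for B-cell, 0.29 for lung epithelial, -0.12 for alveolar macrophage and -0.19 for dendritic genes. The adjusted p then ran from 0.357 to 0.726 and, with fry, from 0.182 to 0.760. The estimated correlations ran from 0.056 (erythroid) to 0.787 (oxidative phosphorylation), and whether their size or the 3 residual degrees of freedom lost each call was not tested. Over the fits without 1 array the medians ran from 0.35 to 0.76 for secondary granule, -0.58 to -0.33 for interferon, -0.42 to -0.29 for MHC class II, -0.50 to -0.39 for B-cell, -0.20 to -0.13 for alveolar macrophage, -0.32 to -0.12 for dendritic, 0.10 to 0.47 for oxidative phosphorylation, 0.12 to 0.19 for erythroid, 0.22 to 0.37 for lung epithelial and -0.19 to 0.02 for inflammatory genes. The first 6 of these lists passed in each of those fits. Lists that passed only in an alternative were, after quantile normalization, immediate-early (-0.14, adjusted p = 0.0149) and T and NK cell genes (-0.10, adjusted p = 0.0333) and, with averaged probe sets, eosinophil genes (-0.06, adjusted p = 0.0493). Without tumour-challenged replicate 1 these were immediate-early (-0.25, adjusted p = 0.000339), suppressive myeloid (-0.09, adjusted p = 0.0328) and fibroblast genes (0.16, adjusted p = 0.0457). Without tumour-challenged replicate 2 they were monocyte (0.27, adjusted p = 0.00715), eosinophil (-0.05, adjusted p = 0.0421) and, in the opposite direction, fibroblast genes (-0.15, adjusted p = 0.0421). Without control replicate 1 they were endothelial (-0.07, adjusted p = 0.0219) and eosinophil genes (-0.05, adjusted p = 0.0404), and without control replicate 2 cell cycle genes (-0.09, adjusted p = 0.0264).

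The labels give both groups replicates 1 and 2 without saying that they pair. Deviations from the group means correlated at 0.285 for the arrays numbered 1 and 0.222 for those numbered 2, but the deviations of 2 arrays mirror each other (-0.285 and -0.222 across the numbers), so these are 2 facts, not 4. Control replicate 3 stands alone in its number, so the fit with the replicate block also drops it, and all its differences equal those without control replicate 3. Changes in the differences from the main fit therefore cannot be put down to the block. The block does alter the standard errors and p-values. At an unadjusted limma p under 0.05 the block fit gave 765 higher and 749 lower, against 436 and 513 without control replicate 3. In the block fit 0 probe sets passed, and the inflammatory list lost its call (median -0.12, camera adjusted p = 0.137, and 0.0809 without control replicate 3). The direction changed for mature neutrophil genes (-0.01), platelet genes (0.00), Nos2 (-0.01) and Ccr2 (-0.03), and the monocyte and fibroblast medians were -0.03 and -0.09. No other call changed.

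Of the lists that passed in the main fit, only the inflammatory median changed sign (0.02 without tumour-challenged replicate 2, 0.00 without control replicate 2). The other directions that changed belong to results that did not pass, and no cause was tested. For lists the direction is that of the test, which need not match the sign of the median. Mature neutrophil genes went to -0.02 with centring, -0.02 with quantile normalization and -0.01 with array weights, with fry turning the test's sign at 0.01. The test for matrix genes, which pointed down in the main fit at a median of -0.01, turned at medians of -0.04 with centring and -0.01 with fry. Fibroblast genes went to 0.01 with fry, and primary granule genes to -0.02 without the dimmest 25%. Without 1 array, medians ran from -0.14 to 0.16 for mature neutrophil, -0.11 to 0.27 for monocyte, -0.25 to 0.14 for immediate-early, -0.12 to 0.01 for endothelial, -0.15 to 0.16 for fibroblast, 0.00 to 0.19 for platelet, 0.03 to 0.24 for hypoxia, -0.04 to 0.27 for ribosomal, -0.08 to 0.04 for matrix, -0.15 to 0.01 for alternative activation, -0.08 to 0.01 for T and NK cell, 0.02 to 0.12 for primary granule, -0.09 to 0.02 for cell cycle and -0.09 to 0.08 for suppressive myeloid genes, and differences from -0.25 to 0.10 for S100a8, -0.20 to 0.04 for S100a9, -0.01 to 0.08 for Nos2, -0.22 to 0.31 for Ccr2, -0.35 to 0.05 for Tgfb1, -0.49 to 0.01 for Igsf6 and -0.05 to 0.63 for Cd14. Of the 46 probe sets past 2-fold, 10 (2 higher and 8 lower) lay below the background level in both groups, where a difference cannot be told from noise: 2 of the 8 are receptor probe sets that set the level.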

Other observations

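The tests on the granule and interferon lists under quantile normalization and of the cell mixture were chosen after those results had been seen, while those on the 3 added lists (granule-stage, MHC class I processing and sterol genes) and on other splits of the arrays were set before their values were seen, though the lists themselves were picked after the main results. Sterol synthesis genes, a group the fixed lists did not hold, were added because Sqle (-1.0 ± 0.15, SE) and Cyp51 (-0.95 ± 0.19, SE), 2 enzymes of the pathway, had large negative differences. Among 14 other measured genes of the pathway and its regulation 9 were negative, and the arrays did not overlap for 6 of these. The other 5 were positive, and the arrays did not overlap for 2 of them, Mvd and Fdps. Msmo1 differed by -0.77 ± 0.19, Hmgcs1, which makes HMG-CoA, by -0.73 ± 0.31 and Fdft1, squalene synthase, by -0.62 ± 0.19 (SE), while Mvd differed by 0.48 ± 0.15; Fdps (positive) and Mvk, Pmvk and Lss (negative) lay below the background level in both groups. The list without Sqle and Cyp51 had a median of -0.22 (camera over the 3 added lists, adjusted p = 0.00851, and adjusted p = 0.552 with an estimated correlation), and medians from -0.31 to -0.13 without 1 array. The list was picked from these same arrays and its genes vary together (estimated correlation 0.618), so its p-values are no independent support. A lower expression of part of the pathway after tumour challenge may be worth a closer look, as a hypothesis found in these 5 arrays.

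For the higher level of secondary and tertiary granule genes, an unequal spread of intensities between arrays is argued against as the whole cause: after quantile normalization the list's median stayed at 0.32 or more in the 5 fits that left out 1 array, more than 0.5 times 0.59. A smaller share of other cells in the sort, with B-cell and dendritic markers lower, was examined by taking mature neutrophil genes to rise alike. The granule median exceeded theirs by 0.30 to 0.94 over the 6 tumour-control array pairs, so the lower end only just passes the bound of 0.30 (0.5 times the list's median). A further condition was added after this margin was seen: without 1 array the granule median ran from 0.35 to 0.76 and theirs from -0.14 to 0.16. Neither condition decides the question, since both were chosen after the results had been seen. Mature neutrophil genes also moved both ways, and bright members such as S100a9 and S100a8 lay where a rise may show less. Their control means were 12.75 and 12.19, against highest array values of 12.89 to 13.49. A smaller share of other cells therefore stays open. A hypothesis is a larger share of neutrophils at the stage that makes these granules. Here 6 other genes linked to that stage had a median of 0.33, with medians from 0.21 to 0.39 without 1 array. Camera over the 3 added lists gave an adjusted p of 0.0252, and of 0.349 with an estimated correlation. This list was picked after the granule genes were seen to be higher, so it cannot tell this hypothesis from other causes. Among these 6 genes Cebpe, a transcription factor of that stage, differed by 0.29 ± 0.08 (SE). Gfi1 and Bpi differed by 0.00, and Orm1 and Bpi lay below the background level in both groups. Cell cycle and primary granule genes did not pass as lists (medians -0.01 and 0.09). Lung epithelial RNA, which was higher and can carry Lcn2, and RNA quality, of which the higher oxidative phosphorylation genes were set as a sign, stay open.

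The lower level of interferon-stimulated genes is not accounted for by the spread of intensities, since the median nearest to 0 over the 5 quantile-normalized fits that left out 1 array was -0.49. Whether the change reaches MHC class I processing genes, which interferons also induce, is open: their median was -0.01 over 9 measured genes (camera adjusted p = 0.281), with B2m at -0.32 ± 0.16 and Psmb10 at 0.34 ± 0.25 (SE), medians from -0.12 to 0.13 without 1 array, and a probe set shared by Psme2 and Psme2b, outside the list and picked after its values were seen, at -1.47 ± 0.70 (SE) with overlapping arrays. Markers of B cells, dendritic cells and alveolar macrophages were lower in the same samples. Fewer of these cells and a lower interferon signal in the sorted myeloid cells themselves cannot be told apart here, because all these cells express such genes. A sort for both CD11b and Gr1 should remove B cells and lung epithelial cells, but Sftpc lay far above the background level in both groups (means 11.74 and 12.24). How pure the sort was is not given in the sources used here.

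The 40 probe sets past 2-fold with no overlap between the groups were set against the other splits of the 5 arrays. Of the 10 splits into 2 and 3 arrays, 1 gave as many, the real one, and the highest of the others gave 24 (control replicates 1 and 3 against the rest). With 10 splits the share is never under 0.1, so the splits are too few to decide. By unadjusted p under 0.05, 3 splits that mix the groups gave more than the 1090 of the real one: 1752 for both arrays numbered 1, 1406 for tumour-challenged replicate 2 with control replicate 3, and 1229 for both arrays numbered 2. What lies behind those splits was not tested.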
